A study of Macaca fascicularis with 6 samples.

How the data were processed

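Oocytes of the cynomolgus monkey were sequenced in 3 groups: GV oocytes, MII oocytes matured in vitro (IVM MII) and MII oocytes matured in vivo (IVO MII), with 2 libraries per group. Per the labels, the oocytes were stripped, wild type and untreated, and cDNA was primed with oligo-dT, extended by template switching, amplified by PCR, tagmented and sequenced as paired reads on a DNBSEQ instrument. The processing notes list fastp, FastQC, Bowtie2, SAMtools and featureCounts. The deposited table holds raw read counts per gene, which, per the file headers, featureCounts 2.0.1 made as fragments over exons by gene, without a strand option, on the RefSeq annotation of the macFas5 genome. Bowtie2 does not split reads over introns, so reads over exon junctions may be missing or may lie in processed pseudogenes, and counts of paralogs share this doubt. No molecular identifiers or added RNA standards are named in the sources used here, so every level is relative to the poly(A)-primed RNA of its own library.

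The table held 28164 genes, of which 0 lay on the mitochondrial genome, so mitochondrially encoded transcripts were not analysed here. Of 11294 genes named only by a LOC identifier, 721 were given a symbol by their gene number from a RefSeq gene table of a later assembly, which was used for names only; coordinates are those of macFas5 in the file. Library totals ran from 27707021 to 35515139 counts. A floor of 3 counts per library, 0.0695 to 0.116 scaled CPM, set the bound for genes without a count. Intervals and floors cover counting error only.

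Genes were filtered by edgeR's filterByExpr, which kept 15815 and left out 12349. edgeR 4.0.16 in R 4.3.3 computed TMM factors (0.903 to 1.22), and its quasi-likelihood test was fitted to all 6 libraries with robust dispersions, with groups as terms. The biological coefficient of variation was 0.232, with 3 residual degrees of freedom and a median prior of 8.81. All tests were two-sided, adjusted by Benjamini and Hochberg over all genes of a comparison at 0.05, with no fold threshold. The p-values measure spread between these libraries; the numbers of oocytes and animals behind a library are not given in the sources used here. Leaving out 1 library leaves a group with a lone library, which is then assumed to vary like the others. No link between replicates of the same number is given in the sources used here, and the main fit assumed none. The correlations between groups of the replicates' deviations were -0.144, 0.178 and -0.114, which cannot exclude a link.

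The groups, the comparisons, 39 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members, 37 of them, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists; camera with an estimated correlation and fry were run beside it. The mitochondrially encoded list had 0 of its 26 symbols in the table. The blood and immune cell list had 21 of 26 in the table and 2 tested, CSF1R at 13.3, 4.93 and 5.40 CPM in GV, IVM MII and IVO MII and MS4A1 below 1 CPM in each. Genes were named if they were among the 8 largest fold changes in either direction of a comparison, with an adjusted p under 0.05, at least 10 CPM in the higher group, both libraries of 1 group above both of the other, and a symbol. Up to 3 genes per direction of each list, by adjusted p, and any landmark oocyte gene could also be named.

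The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals, no low-count filter, a strict filter of 10 CPM in 2 libraries, the 4 compared libraries alone, the replicate number as a block, each library left out, a non-robust fit and a fold above 2. An offset removing the trend with gene length was added after seeing the data. The procedure was tested on simulated data made from these libraries. Figures were drawn with matplotlib 3.10.9.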

Results

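The data are gene counts from RNA sequencing of oocytes of the cynomolgus monkey (Macaca fascicularis), in 3 groups of 2 libraries each. GV oocytes are immature, held in prophase of the first meiotic division with an intact nucleus, the germinal vesicle. IVM MII oocytes had matured to metaphase of the second meiotic division in culture, and IVO MII oocytes had reached that stage in the animal. The cDNA was primed on poly(A) tails and amplified by a full-length, template-switching (Smart-seq) method, and the oocytes were stripped of their surrounding cells. The GV libraries held 31421282 and 32777458 counts, the IVM MII libraries 35515139 and 33875153, and the IVO MII libraries 27707021 and 29354497. A count was found for 20070 and 20082 genes in the GV libraries, 18986 and 18943 in IVM MII, and 18264 and 18313 in IVO MII. Of the 28164 genes in the table, 15815 had enough counts to be tested. All expression levels below are CPM (library-size-scaled counts, with TMM factors), as means of n = 2 libraries; a value after ± is the SD of a CPM mean or, for a log2 fold change, the standard error from the fit.

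The libraries of a group were more alike than libraries of different groups. The correlation of log2 CPM across genes was 0.975 to 0.982 within groups, 0.930 to 0.936 between IVM MII and IVO MII, 0.875 to 0.895 between IVM MII and GV, and 0.847 to 0.876 between IVO MII and GV. These correlations are across genes, which are not independent replicates. The first principal component held 61.5% of the variance and the second 24.9%.

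**Figure D1:**
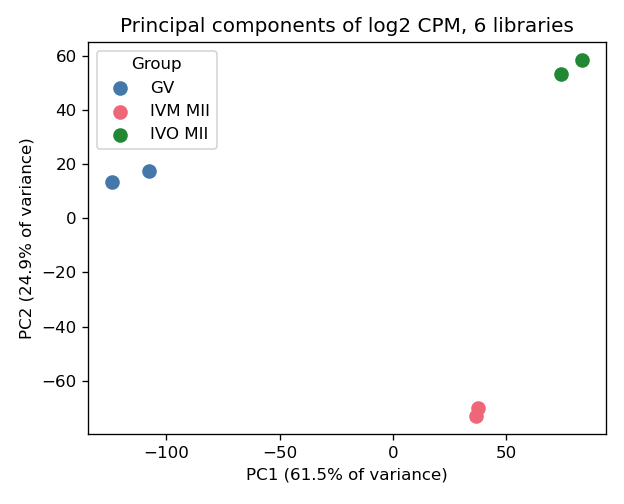
Scores of the 6 libraries on the first and second principal components of log2 CPM (no unit), coloured by group, each point a library. The points of each group lie side by side, and the axes hold 61.5% and 24.9% of the variance.

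The comparison of IVM MII with IVO MII asks how oocytes matured in culture differ from those matured in the animal. The respiratory chain and mitochondrial ribosome lists were higher in IVM MII by camera at its preset correlation, the only 2 of 37 gene lists to pass. Neither passed with an estimated correlation (adjusted p = 0.931 for each), and fry called 0. The respiratory chain subunit NDUFA1 stood at 25.4 CPM in IVM MII and 2.43 in IVO MII, 10.4-fold higher. The mitochondrial ribosomal protein MRPL33 stood at 111 ± 33.5 against 5.59 ± 2.76 CPM, 19.8-fold higher. WEE2, the oocyte kinase that inhibits CDK1, went the other way, with 2988 CPM in IVM MII and 9789 in IVO MII. In all, 2260 genes were higher and 1635 lower in IVM MII, 24.6% of the genes tested. Changes of more than 2-fold made up 1844 of the higher and 1109 of the lower genes.

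Among genes with a symbol and at least 10 CPM in the higher group, the largest fold change upward was that of ANTXR2, a cell-surface receptor for collagen VI (macFas5 chromosome 5, 54430399 to 54588113), at 24.9 ± 3.68 CPM in IVM MII and 0.425 ± 0.601 in IVO MII. Its log2 fold change was 5.80 ± 0.70 with an adjusted p of 2.22e-04, and it rested on 25 counts over both IVO MII libraries. It was 4.87 without IVO MII replicate 1, which had no count of ANTXR2; without IVO MII replicate 2 the group is at 0, so no fold change is given. ST8SIA4, a polysialic acid transferase (chromosome 6, 99311528 to 99413917), was 42.1-fold higher, with a log2 fold change of 5.40 ± 0.40. MS4A4A, a membrane protein, was 37.1-fold higher and CCM2L, an adaptor known from endothelium, 27.3-fold higher. MTERF4, a factor of mitochondrial ribosome assembly, was 20.4-fold higher, L3MBTL4, a chromatin reader, 18.9-fold, and ZBED1, a zinc finger transcription factor, 18.2-fold. Lower in IVM MII were GAP43, a growth cone protein (chromosome 2, 156527560 to 156628909), and RERG, a Ras-like GTPase. Neither had a count in IVM MII, where a floor of 3 counts per library makes GAP43 at least 234-fold and RERG at least 131-fold lower than the 18.1 and 10.1 CPM of IVO MII. CYP4V2, a fatty acid hydroxylase (gene identifier LOC102141321), had 3 counts over both IVM MII libraries and 1858 over both IVO MII libraries. The cytokine gene IL17B was 27.4-fold lower in IVM MII, GATB, a subunit of the enzyme that makes mitochondrial glutaminyl-tRNA, 24.7-fold, and UBXN8, an adaptor of the ATPase VCP, 18.5-fold. FAM111B, a protease, was 11.2-fold lower, and DUSP2, a phosphatase of MAP kinases, 14.7-fold lower with a log2 fold change of -3.88 ± 0.47. DUSP2 was at -3.81 with an adjusted p of 0.0683 without IVO MII replicate 2, and at -3.23 and -4.93 without IVM MII replicates 1 and 2. Without IVO MII replicate 2 MRPL33 was at 4.95 in place of 4.31. The counts of CYP4V2 in IVM MII all lay in replicate 2 (0.0852 CPM), at the floor, so no fold change is given for it.

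The nuclear-encoded respiratory chain list held 78 symbols, of which 62 were in the table under those names. Older names were not added, so ATPIF1, an older name of the listed ATP5IF1, was not counted as a member. Of these 62 genes, all tested, 27 were higher and 0 lower by the edgeR test, and 32 and 1 when adjusted over the list alone. NDUFA7 was 6.84-fold higher and NDUFB5 4.49-fold higher. The median log2 fold change was 0.71, with a camera adjusted p of 5.02e-08, and an adjusted p = 0.931 with an estimated correlation. Of 72 mitochondrial ribosomal protein genes, 24 were higher and 1 lower (25 and 2 adjusted over the list alone), with a median of 0.53 and an adjusted p of 7.76e-04 (adjusted p = 0.931 with an estimated correlation). MRPS28 was 4.06-fold higher and MRPS6 2.65-fold higher, while MRPL30 was 2.67-fold lower. With an estimated correlation, 0 of the 37 lists passed camera, 0 had an unadjusted p under 0.05, and fry called 0. Fold changes also fell with gene length across all genes (Spearman's rho -0.13), and an alternative chosen after seeing the data that removes this trend left medians of 0.41 and 0.25, with adjusted p of 1.41e-04 and 0.0419. The pyruvate dehydrogenase subunit PDHA1 was 4.15-fold higher in IVM MII, and PDK1, the kinase that turns that enzyme off, was 3.00-fold lower, at 958 against 2876 CPM. Over the 32 pyruvate and tricarboxylic acid cycle genes, 7 were higher and 4 lower, and the list did not pass (adjusted p = 0.828).

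The genes of the cell cycle and of chromosome segregation moved in both directions. CDK1, the kinase of M phase, was 3.55-fold higher in IVM MII and its partner cyclin CCNB2 2.36-fold higher, while WEE2 was 3.28-fold and cyclin CCNA2 2.13-fold lower. Of the 38 meiotic kinase and cyclin genes, 7 were higher and 5 lower, with a camera adjusted p of 0.908. Of 30 cohesin and chromosome segregation genes, 2 were higher and 6 lower (2 and 7 adjusted over the list alone). The cohesin acetyltransferase ESCO1 was 3.46-fold and the cohesin subunit STAG1 2.48-fold lower, and the list did not pass (adjusted p = 0.120). Of 50 chromatin modifier genes, 3 were higher and 9 lower (5 and 13 adjusted over the list alone), with an adjusted p of 0.138. The acetyltransferase KAT2A was 6.16-fold lower, the methyltransferase SETD2 4.56-fold, and ARID1A, a subunit of the SWI/SNF remodeller, 2.30-fold. TET3, which oxidises methylcytosine, was at 53.4 CPM in IVM MII and 136 in IVO MII, 2.54-fold lower.

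Among oocyte genes, the egg coat gene ZP3 was at 4932 CPM in IVM MII and 1610 in IVO MII, 3.06-fold higher. Its call ended without IVO MII replicate 1, where its log2 fold change was 1.26 with an adjusted p of 0.0624. NLRP2 and NLRP7, genes of the oocyte NLRP family, were 2.97-fold and 3.27-fold higher, and ASTL, the egg's ovastacin protease, was 6.23-fold higher. Of the 14 subcortical maternal complex and NLRP genes, 5 were higher and 2 lower (adjusted p = 0.519). The chaperones HSPA5 and HSPA8 were 5.44-fold and 2.80-fold higher. Over the 34 heat shock and unfolded protein response genes, 8 were higher and 2 lower, or 9 and 2 adjusted over the list alone, and the list did not pass (adjusted p = 0.413). The lower genes were HSPB1 (log2 fold change -1.08) and HSP90AB1 (-0.83). The call of HSPB1 ended without IVM MII replicate 2 (-0.74) or IVO MII replicate 2 (-0.47), and that of HSP90AB1 without IVM MII replicate 1 (-0.80) or 2 (-0.84) or IVO MII replicate 1 (-0.54). Library totals ended both calls as well. The 4 compared libraries alone and the replicate block also ended that of HSPB1. SOD2, the mitochondrial superoxide dismutase, was 2.38-fold lower (247 against 586 CPM) and NNT, which supplies mitochondrial NADPH, 10.7-fold lower, while TXNRD1 was 4.51-fold and GLRX2 3.89-fold higher. Over the 35 antioxidant genes, 11 were higher and 3 lower (adjusted p = 0.246). The actin regulator PFN1 was 6.44-fold lower, while ARPC3 was 7.15-fold higher.

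Markers of other ovarian cells were compared as well. GREM1, a cumulus cell transcript, was at 29.0 ± 5.28 CPM in IVM MII and 4.01 ± 1.16 in IVO MII, 7.25-fold higher, and RUNX2 was 3.95-fold higher. HAS2 stood at 18.7 and 22.2 CPM and FSHR at 3.89 and 2.76 in IVM MII and IVO MII, and neither differed by the test. Of 14 cumulus and granulosa markers tested, 3 were higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.722). VWF, an endothelial marker, was 2.35-fold higher in IVM MII (103 against 43.9 CPM) and stood at 312 CPM in GV. Of the 10 theca, stroma and endothelium markers, 1 was higher and 1, OGN, was lower in IVM MII (adjusted p = 0.908). OGN had a log2 fold change of -0.95, and its call ended without either GV replicate (-0.95 each), either IVM MII replicate (-0.88 and -0.99) or IVO MII replicate 1 (-0.80). Library totals and the 4 compared libraries alone also ended the call of OGN.

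The numbers of genes called depended on single libraries and on the scaling. Without IVM MII replicate 2 the genes higher and lower numbered 1327 and 753, and without IVM MII replicate 1 the lower genes numbered 895; without IVO MII replicate 2, 4 lists passed in place of 2. Scaling by library totals moved the median log2 fold change of all genes from 0.02 to 0.24. It gave 2803 higher and 894 lower genes, 75.8% higher in place of 58.0%. RLE factors gave 2076 higher and 1945 lower genes (51.6% higher), and DESeq2 2100 and 2136 (49.6%). With the gene length trend removed there were 1979 and 2076 (48.8%), so the excess of higher genes depended on the processing. Library totals reversed no named gene with a call and no camera direction of a passing list.

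The comparison of IVM MII with GV follows maturation in culture. By camera at its preset correlation, 7 lists were lower in IVM MII, among them the respiratory chain, mitochondrial ribosome, glycolysis, tricarboxylic acid cycle and subcortical maternal complex lists, though members of most went both ways. The 5 lists that were higher were histones and their chaperones, splicing, cohesin, the spindle checkpoint and deadenylation. With an estimated correlation 0 of these 12 lists passed, the lowest adjusted p being 0.647. HADHA, a subunit of the enzyme of mitochondrial fatty acid oxidation, went from 1874 CPM in GV to 68.3 in IVM MII, 27.4-fold lower. In all, 4053 genes rose and 3908 fell, 50.3% of those tested. Of these, 2756 rose and 3450 fell more than 2-fold, and 99 rose and 743 fell more than 8-fold. Rises and falls from GV, here and for IVO MII below, are relative to the poly(A)-primed RNA of each library. Capture that follows poly(A) tail length was not told apart from a change in RNA amount.

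Among genes with a symbol and at least 10 CPM in the higher group, the largest rise was in GALNT5, which starts mucin-type glycosylation (chromosome 12, 46024017 to 46081391), from 6.02 ± 0.187 to 160 ± 18.8 CPM, with a log2 fold change of 4.73 ± 0.25 and an adjusted p of 8.13e-07. CNTNAP5, of the neurexin family, rose 22.5-fold. SULT2A1, a steroid sulfotransferase, and TMEM233 rose 10.4-fold each. ULBP3, a ligand of the receptor NKG2D, had a log2 fold change of 3.33, and GTPBP8 rose 9.96-fold, CCDC90B, of mitochondria, 9.51-fold, and the co-chaperone DNAJB4 9.18-fold. The largest fall was in CD69, a C-type lectin (chromosome 11, 10117853 to 10124608), from 37.1 ± 3.71 to 0.0968 ± 0.104 CPM. Its log2 fold change was -8.62 ± 0.55, resting on 7 counts in IVM MII, and -7.69 without IVM MII replicate 1. Replicate 1 had CD69 at 0.0232 CPM, under the floor of 3 counts, so no fold change without replicate 2 is given. FAM92B fell 54.7-fold, NINJ2, an adhesion protein, 46.5-fold, KRBOX1 38.8-fold, the galectin LGALS4 36.8-fold, and SSSCA1 36.1-fold. GPN1, which serves nuclear import of RNA polymerase II, fell from 748 ± 98.2 to 23.9 ± 2.20 CPM, 31.3-fold. CSRP1, a LIM domain protein, fell 36.4-fold. The log2 fold change of CSRP1 was -5.19 with all libraries and -7.03 and -4.40 without IVM MII replicates 1 and 2, and its call ended without IVO MII replicate 1 (adjusted p = 0.0576) or replicate 2 (adjusted p = 0.0699).

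Of the 62 respiratory chain genes, 39 fell and 10 rose (39 and 12 adjusted over the list alone), with a median of -1.85 and an adjusted p of 2.22e-09 (adjusted p = 0.708 with an estimated correlation). UQCRC1 fell 26.0-fold, COX8A 17.6-fold and NDUFA9 16.3-fold, while NDUFB3 rose 3.00-fold. Of the 72 mitochondrial ribosomal protein genes, 38 fell and 7 rose (the same adjusted over the list alone), with a median of -1.08 and an adjusted p of 2.83e-07 (adjusted p = 0.708 with an estimated correlation). MRPS11 fell 24.4-fold and MRPL35 14.3-fold. The other 10 passing lists had adjusted p of 0.0409 to 0.0478, and with an estimated correlation the adjusted p of each was 0.647 or higher. Adjusted over the list alone, 20 deadenylation and 29 splicing genes rose, and the counts of the other 8 lists were those given here. With an estimated correlation 0 of the 37 lists passed camera and 0 had an unadjusted p under 0.05, while fry called 22. In the glycolysis and pentose phosphate list 13 of 23 genes fell and 5 rose. GPI fell 18.9-fold, GAPDH 17.4-fold and ENO1 11.2-fold, and the lactate transporter SLC16A1 rose 2.65-fold. In the pyruvate and tricarboxylic acid cycle list 15 of 32 genes fell and 6 rose, with MPC1, a subunit of the pyruvate carrier, 12.8-fold lower. In the proteasome list 14 of 36 genes fell and 9 rose. The proteasome list's test was for a fall and its mean was -0.66, but its median was 0.03.

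The subcortical maternal complex and oocyte NLRP list, which holds proteins needed for early cleavage, had 5 of 14 genes that fell and 0 that rose. NLRP5 fell from 505 to 85.9 CPM, OOEP from 3849 to 742, and PADI6 4.90-fold. PADI6 had a log2 fold change of -2.29, and of -1.63 without GV replicate 2. Of the 35 landmark oocyte genes, 17 fell and 6 rose. GDF9, the growth factor by which oocytes signal to cumulus cells, fell 3.09-fold. IZUMO1R, the sperm receptor, fell 10.4-fold, the transcription factor FIGLA 9.44-fold, and ZAR1, a binder of stored mRNA, 4.61-fold. Among the genes that rose, CPEB1, which binds the cytoplasmic polyadenylation element, went from 329 to 682 CPM. In the mRNA deadenylation and decay list 19 of 34 genes rose and 4 fell, with the decapping enzyme DCP2 2.75-fold, the exonuclease XRN1 3.66-fold and the deadenylase CNOT6L 2.57-fold higher. In the splicing list 28 of 55 rose and 8 fell, with SRSF11 2.70-fold higher and SF3B5 18.3-fold lower. In the histone and chaperone list 19 of 33 rose and 3 fell, with H2AX 6.56-fold higher. In the cohesin and segregation list 14 of 30 rose and 1 fell, with SMC1B, the meiotic cohesin subunit, 3.85-fold higher. In the spindle checkpoint and kinetochore list 14 of 34 rose and 3 fell, with CENPA, the centromeric histone, 4.01-fold higher and BIRC5 3.05-fold lower.

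Of 14 cumulus and granulosa markers, 4 were higher in IVM MII than in GV and 1 was lower (adjusted p = 0.289). GREM1 was 7.31-fold and HAS2 3.75-fold higher, with GV at 3.97 and 4.99 CPM, while VWF was 3.03-fold lower; of the 10 theca, stroma and endothelium markers 1 was higher and 2 were lower (adjusted p = 0.812). Without GV replicate 2 the genes that rose numbered 2580 and 6 lists passed, the cohesin, glycolysis, deadenylation, splicing, proteasome and spindle checkpoint lists losing their call. The tricarboxylic acid cycle, maternal complex, proteasome and spindle checkpoint lists lost theirs without IVM MII replicate 1, where 8 passed, and the cohesin, glycolysis, maternal complex and proteasome lists without IVM MII replicate 2, where 9 passed. Under library totals 7 lists passed, the median of all genes moved from 0.06 to 0.35, and 5272 genes rose and 3004 fell (63.7% higher in place of 50.9%); under a strict low-count filter 2 passed, the respiratory chain and mitochondrial ribosome lists. Fold changes here rose with gene length (Spearman's rho 0.22), and with that trend removed 7 lists passed, the respiratory chain median being -1.28 and the mitochondrial ribosome median -0.72.

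**Figure D2:**
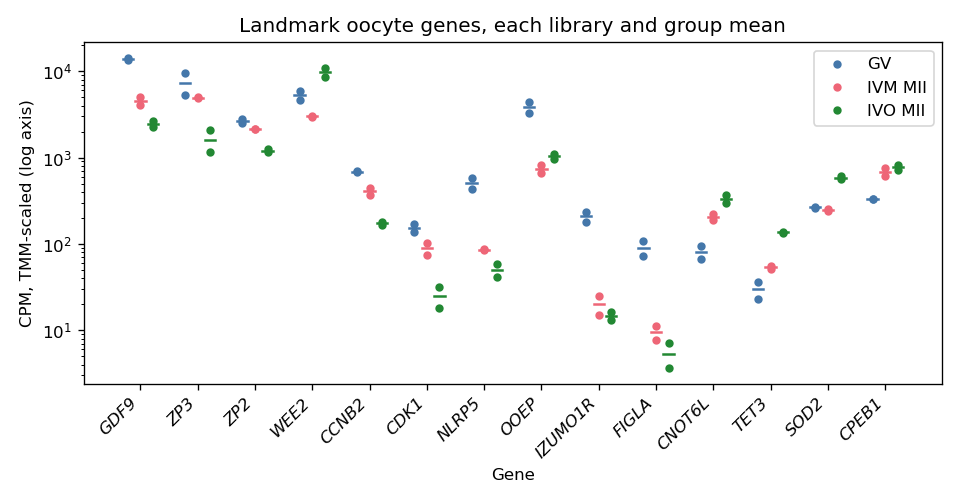
TMM-scaled CPM (log axis) of 14 oocyte genes in each library, coloured by group, with a bar at each group mean. GDF9 falls from 13924 CPM in GV to 4504 in IVM MII and 2452 in IVO MII, and CNOT6L is higher in both MII groups than in GV.

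The comparison of IVO MII with GV follows maturation in the animal. By camera at its preset correlation, 8 lists were higher in IVO MII: deadenylation, splicing, histones, cohesin, the spindle checkpoint, chromatin modifiers, DNA repair and DNA methylation. The 7 lists that were lower were the respiratory chain, mitochondrial ribosome, tricarboxylic acid cycle, maternal complex, antioxidant, landmark and proteasome lists. With an estimated correlation 0 of these 15 lists passed, the lowest adjusted p being 0.445. The chromatin modifier, antioxidant, DNA repair and DNA methylation lists did not pass in IVM MII against GV (adjusted p of 0.0597, 0.136, 0.223 and 0.202), and glycolysis, which passed there, did not pass in IVO MII (0.180). No difference between the MII groups was shown for these 5 lists by the list test (adjusted p of 0.138, 0.246, 0.447, 0.519 and 0.734). PDHA1 went from 168 CPM in GV to 5.78 in IVO MII, 29.0-fold lower. In all, 4442 genes rose and 4816 fell, 58.5% of those tested, and 74 rose and 1064 fell more than 8-fold.

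Under the same naming rule, the largest rise was in CYP4V2 (chromosome 5, 185606712 to 185627744), which had no count in GV and stood at 33.8 ± 4.51 CPM in IVO MII, at least 332-fold higher by the floor of 3 counts per library. CACNG7, a regulator of AMPA receptors and calcium channels, rose 24.1-fold, with a log2 fold change of 4.59 ± 0.46 and an adjusted p of 1.14e-05. KCTD13, an adaptor of a ubiquitin ligase, rose 13.9-fold, the transcription factor SIX2 12.1-fold, and INPP5E, a lipid phosphatase of cilia, 11.2-fold. The netrin receptor UNC5A rose 9.30-fold and the cytokine TNFSF12 9.15-fold. The largest fall was in LGALS4 (chromosome 19, 39278395 to 39289578), from 42.8 ± 2.07 to 0.341 ± 0.0456 CPM, with a log2 fold change of -6.95 ± 0.35. C4H6orf52 fell from 3596 ± 63.1 to 65.1 ± 3.15 CPM, 55.2-fold. STARD5, a lipid transfer protein, fell 58.5-fold, KRBOX1 52.0-fold, SSSCA1 51.1-fold, ATPIF1, the inhibitor of mitochondrial ATP synthase, 45.9-fold, DNAJC5G 43.3-fold, and the fatty acid binder FABP5 38.3-fold. KRBOX1 had a log2 fold change of -5.70, and of -4.73 without IVO MII replicate 2; replicate 2 had KRBOX1 at 0.034 CPM, under the floor, so no fold change without replicate 1 is given. SSSCA1 had -5.67, and -6.45 without IVO MII replicate 2.

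In IVO MII, 45 of the 62 respiratory chain genes fell and 4 rose (47 and 4 adjusted over the list alone), with a median of -2.60 and an adjusted p of 7.06e-18 (adjusted p = 0.445 with an estimated correlation). NDUFA1 fell 21.9-fold and COX7B 13.8-fold. Of the 72 mitochondrial ribosomal protein genes, 53 fell and 7 rose (53 and 8 adjusted over the list alone), with a median of -1.89 and an adjusted p of 1.77e-11 (adjusted p = 0.527 with an estimated correlation). The other 13 passing lists had adjusted p of 0.00163 to 0.0379, and with an estimated correlation the adjusted p of each was 0.445 or higher. Adjusted over the list alone, 20 cohesin genes rose, 10 maternal complex genes fell, 7 tricarboxylic acid cycle genes rose and 4 DNA methylation genes fell, other counts being those given here. With an estimated correlation 0 of the 37 lists passed camera and 1 had an unadjusted p under 0.05, while fry called 27. Of the 35 antioxidant genes 18 fell and 7 rose, with the peroxiredoxin PRDX2 18.0-fold and GSTM3 12.8-fold lower and GSR, the glutathione reductase, 3.18-fold higher. Of 36 proteasome genes 21 fell and 12 rose, with PSMB1 21.7-fold lower. Of the 32 pyruvate and tricarboxylic acid cycle genes 14 fell and 6 rose. Of the 14 subcortical maternal complex genes 9 fell and 1 rose, with NLRP5 10.1-fold and TLE6 5.81-fold lower.

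Of 30 cohesin and segregation genes 19 rose and 4 fell, with STAG1 4.11-fold and PDS5B 4.10-fold higher and CDCA5 2.34-fold lower. Of 50 chromatin modifier genes 27 rose and 9 fell, with the methyltransferase KMT2D 5.04-fold and the bromodomain gene BRD2 4.37-fold higher. Of 34 deadenylation and decay genes 19 rose and 6 fell, with CNOT6L 4.13-fold and DCP1A 3.99-fold higher. Of 34 spindle checkpoint genes 17 rose and 4 fell, of 33 histone and chaperone genes 14 rose and 7 fell, and of 55 splicing genes 32 rose and 9 fell. Of 47 DNA repair genes 24 rose and 8 fell, with RPA1 3.50-fold higher and RPA2, of the same complex, 6.07-fold lower. Of 21 DNA methylation genes 10 rose and 3 fell, with TET3 4.56-fold higher. Of 35 landmark genes 20 fell and 10 rose. GDF9 fell 5.68-fold, ZP3 4.56-fold, CDK1 6.19-fold and CCNB2 3.95-fold, and SOD2 rose 2.22-fold.

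Of 14 cumulus and granulosa markers, 3 were higher in IVO MII than in GV and 2 lower, or 2 and 1 adjusted over the list alone (adjusted p = 0.696). HAS2 was 4.44-fold higher, with a log2 fold change of 2.15, and of 1.36 without IVO MII replicate 2. VIM was 3.24-fold lower. Of 10 theca, stroma and endothelium markers, 4 were higher in IVO MII than in GV and 2 lower, the same adjusted over the list alone (adjusted p = 0.857); VWF was 7.11-fold lower, and TEK was higher, at 179 CPM against 106. The log2 fold change of TEK was 0.76, and its call ended without GV replicate 2 (0.61) or IVO MII replicate 1 (0.67). The strict low-count filter also ended the call of TEK. Fold changes rose with gene length (Spearman's rho 0.26), with a median of -0.94 in the shortest decile of genes. With that trend removed the respiratory chain median was -1.68 in place of -2.60 and the mitochondrial ribosome median -1.20 in place of -1.89. The genes that rose and fell then numbered 4860 and 4240, 53.4% higher in place of 48.0%. Library totals gave 4577 and 4440 (50.8%). Under a strict low-count filter 8 lists passed, and with the gene length trend removed 7 passed: the respiratory chain, mitochondrial ribosome, cohesin, histone, splicing, spindle checkpoint and maternal complex lists. Without GV replicate 2, or without IVO MII replicate 1, 12 lists passed. The DNA repair and DNA methylation lists lost their call in each case, as did the splicing list without GV replicate 2 and the antioxidant and tricarboxylic acid cycle lists without IVO MII replicate 1.

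**Figure D3:**
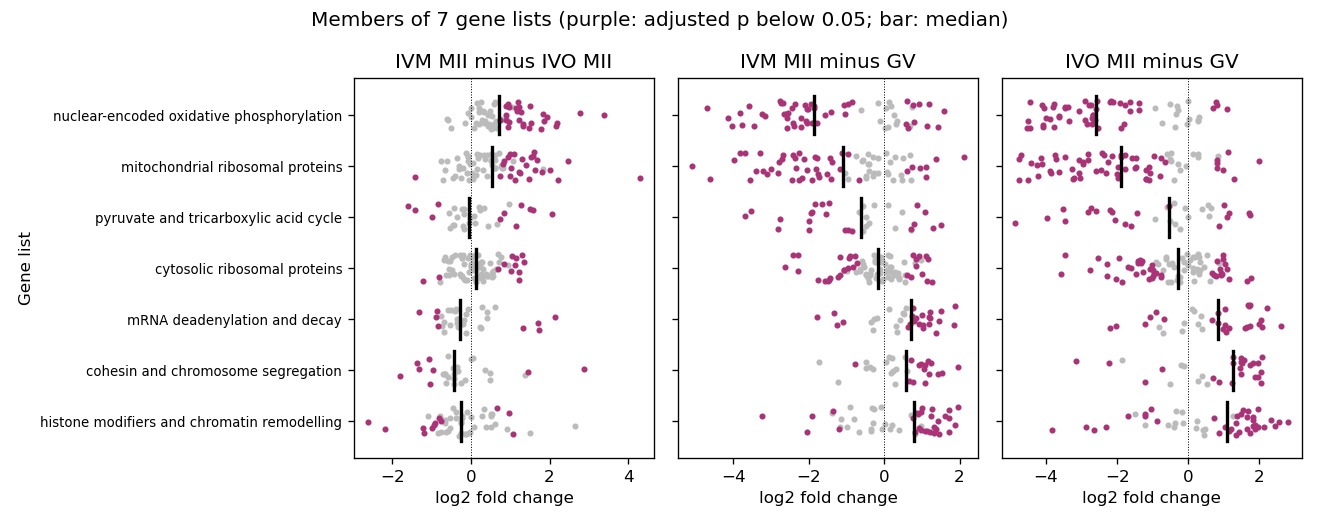
Log2 fold change (no unit) of each tested member of 7 gene lists in the 3 comparisons, each point a gene, purple where the adjusted p passed 0.05 and grey where it did not, with a bar at the median. The bars of the respiratory chain list stand at 0.71, -1.85 and -2.60, and those of the mitochondrial ribosome list at 0.53, -1.08 and -1.89.

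Both routes of maturation were then set side by side. The changes from GV in IVM MII and in IVO MII were correlated across 15815 genes (Pearson's r = 0.690, Spearman's rho = 0.742), which are not independent replicates. Both changes use the same GV libraries. Simulated groups without change against those libraries gave r = 0.502 ± 0.011 (SD over 20 simulations). Sharing a control gives such an r by itself, so it is not a share of the 0.690. The simulated covariance was 0.0942 in place of 1.79, so by covariance the shared controls alone gave a small part of the agreement. Genes higher in both numbered 2965 and genes lower in both 3088, where 1138 and 1190 would be shared by independent calls. In the simulated groups at most 1 gene was called in both. Across genes, the change in IVM MII rose by 0.62 for each unit of the change in IVO MII. The median gene that changed in IVO MII showed 0.70 of that change in IVM MII, with quartiles of 0.41 and 0.95. These genes were chosen by their change in IVO MII, which is also the divisor. The 0.62 and the 0.70 can thus lie under 1 without a difference between the routes, and the reverse values were not computed. TET3 stood at 29.8 CPM in GV, 53.4 in IVM MII and 136 in IVO MII, and NLRP5 at 505, 85.9 and 49.8 CPM.

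Among the 3895 genes that differed between IVM MII and IVO MII, the IVM MII level lay nearer GV in 2640, or 67.8% (exact binomial 95% interval 66.3 to 69.2). That interval takes the genes as independent, which they are not, and leaves out differences between libraries. The percentage was 68.9 among genes higher and 66.2 among genes lower in IVM MII, and 61.3 among all genes tested. Nearer does not mean intermediate: the IVM MII level lay between GV and IVO MII in 1763 of the 3895 genes (45.3%), beyond IVO MII in 588 (15.1%) and on the other side of GV in 1539 (39.5%). Of those 1539 genes, 877 were nearer GV in IVM MII and so are among the 2640. NLRP2, CDK1, CCNB2 and ZP3 lay between GV and IVO MII in the IVM MII libraries, at 727, 88.7, 408 and 4932 CPM. Calls against GV in opposite directions were made for 205 genes that also differed between the MII groups, 124 higher in IVM MII and lower in IVO MII and 81 the reverse. UBXN8, for example, fell from 35.3 CPM in GV to 5.62 in IVM MII and rose to 104 in IVO MII.

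**Figure D4:**
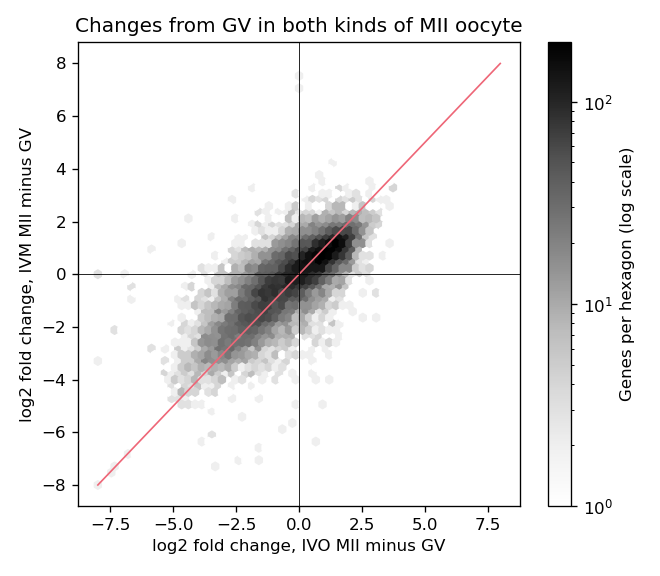
Log2 fold change from GV (no unit) in IVM MII against that in IVO MII for 15815 genes, as counts per hexagon on a log colour scale, with values limited to 8 in size and a red line where both are equal. The slope of the IVM MII change on the IVO MII change was 0.62, which alone shows no difference between the routes. The correlation is 0.690.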

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

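Of the tests below, those of the respiratory chain and mitochondrial ribosome lists were written before their results were seen, while the removal of the gene length trend was chosen afterwards. The results here differ between the IVM MII and IVO MII groups in their change from GV, by the edgeR test of that difference, which is the comparison of IVM MII with IVO MII itself.

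Higher in IVM MII were ST8SIA4 (log2 fold change 5.40), MS4A4A (5.21), CCM2L (4.77), MTERF4 (4.35), L3MBTL4 (4.24) and ZBED1 (4.19). Lower were GATB (-4.63), UBXN8 (-4.21) and DUSP2 (-3.88), with GAP43 at least 234-fold and RERG at least 131-fold lower by the floor of 3 counts per library. The call of DUSP2 ended without IVO MII replicate 2, at -3.81 with an adjusted p of 0.0683, and its value was -3.23 and -4.93 without IVM MII replicates 1 and 2. No explanation was tested for these single genes. Calls against GV in opposite directions were made for 205 genes. UBXN8 was among them, at 35.3 CPM in GV, 5.62 in IVM MII and 104 in IVO MII.

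The medians of the respiratory chain list (0.71) and the mitochondrial ribosome list (0.53) were higher in IVM MII than in IVO MII. Each median lay above nearly all of 10000 random lists matched on length and expression, at percentiles 99.99 and 99.67. With genes that vary independently this would argue against a bias by gene length alone. Because of the correlation between genes given below, such a bias stays open. A smaller version of the fall seen in the animal stays open for both lists. The respiratory chain median lay at percentile 99.35 of lists matched on that fall. With the IVO MII libraries exchanged it lay at 97.98, a median of 0.71 against an upper limit of 0.70. The mitochondrial ribosome median lay at 91.6 and 76.1. The fall matched on was that of a single IVO MII library, so matched genes may have a smaller true fall. Random lists for length and for the fall were drawn gene by gene. Their limits thus leave out correlation between genes, estimated at 0.19 and 0.18 for the 2 lists. Both lists lose their camera call with an estimated correlation (adjusted p = 0.931 for each). Oligo-dT capture that follows poly(A) tail length, and the animals and handling behind each group, stay open and were not tested.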

How the results depend on the processing

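Of the alternatives here, the removal of the gene length trend was chosen after seeing the data. No direction of a named gene with a call, and no camera direction of a list that passed, was reversed under the alternatives run. Sign changes of named genes without a call were not counted. The proteasome list, lower by camera in IVM MII against GV, had a median of 0.49 with the length trend removed. Lists that did not pass could turn: with the length trend removed the cytosolic ribosomal protein list, with medians of 0.13, -0.17 and -0.29 in the 3 comparisons, had -0.16, 0.39 and 0.50. Of the summary results under an alternative, 143 stayed within their bounds and 36 left them: 1.5 times for a count, the 95% interval for the percentage nearer GV, and 1 SD over single-library values for the correlation. The percentage stayed above 50 and the correlation above 0 in each; of named gene and list results 10968 kept their side, 520 lost their call and 19 gained one. With 1 library left out, IVM MII against IVO MII gave 1327 to 2094 higher and 753 to 1496 lower genes and 2 to 4 lists, IVM MII against GV 2580 to 4452, 2752 to 4264 and 6 to 13, and IVO MII against GV 3370 to 4435, 3729 to 4875 and 12 to 15. The percentage nearer GV was then 63.2 to 70.2 and the correlation 0.620 to 0.698. Library totals gave 894 genes lower in IVM MII than IVO MII, 7 lists for IVM MII against GV and 61.6% nearer GV. The strict filter, which tests fewer genes, gave 1051 lower genes between the MII groups, 2268 and 2352 for IVM MII against GV with 2 lists, 2727 and 2859 for IVO MII against GV with 8 lists, 74.3% and a correlation of 0.804. The length offset gave 66.0% and 7 lists in each comparison with GV; DESeq2 gave 69.6%, a fold above 2 65.0%, no filter a correlation of 0.608 and the 4 compared libraries 0.746. With an estimated correlation 0 lists passed in each comparison. The replicate block gave 2180 higher and 1545 lower genes between the MII groups. Apart from the filter, the cause was not tested. In simulated data at this depth and group size, 200 of 15241 to 15249 genes were changed. Of these, 0 were found at 1.5-fold, 13.5% at 2-fold and 90.5% at 4-fold, with 0, 1 and 11 false calls. In the data at least 24.6% of the genes tested were called, so the adjustment was stricter in the simulation. Its rates are thus not those of the tests above.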

Other observations

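The tests in this part were chosen after the nearness of IVM MII to GV was seen. IVM MII lay nearer GV in 67.8% of the genes that differ between the MII groups. Scaling is argued against as the cause of a percentage above 50, since the lowest over the scalings was 61.6, with library totals. All genes tested gave 61.3 with TMM factors, and that share was not computed under the other scalings. Whether the excess over it depends on scaling thus stays open. The slope of IVM MII minus 1 IVO MII library on the other minus GV was -0.293, and -0.248 with them exchanged. Noise of a single IVO MII library alone would not give this negative slope. Changes only partly shared by the routes can give it, so it cannot decide whether such noise raised the percentage. A deviation shared by both IVO MII libraries would also give a negative slope and stays open. GV RNA mixed into IVM MII at a share of 57.7% is argued against. Of the genes at 10 CPM or more in GV, 22.0% lay under that share of their GV level in both IVM MII libraries. The share was a median over 954 genes chosen as higher in IVM MII than in IVO MII and lower in IVO MII than in GV. That choice favours a large share, so a mixture at a smaller share stays open. The slope of the IVM MII change on the IVO MII change was 0.691 between separate libraries. It cannot decide whether changes go less far in culture. Changes that are only partly shared can give a slope under 1 in either direction, and the reverse slope was not computed. Shorter changes alone are argued against by the 16.0% of differing genes with a called change from GV in IVM MII, away from IVO MII. A less complete course for other genes stays open, as do animals, timing and handling, which were not tested.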
